A study of Mus musculus with 6 samples.

How the data were processed

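Poly(A)-selected RNA libraries of 6 mouse kidneys, 3 labelled Control and 3 labelled KC-Tie2, were analysed from the deposited processed tables. Samples were grouped by the genotype in their labels, and columns were matched to samples by the library names in the sample descriptions. The labels give no sex, strain, age, litter or batch, and do not say whether the samples of a genotype are separate animals.

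The deposited expression values are a signal on a normalized scale: per the submitters' processing notes the tools were Partek 12.5.0, STAR and DESeq2 with the build mm39, and which tool made which step is not given in the sources used here. In the deposited table, 68.2% to 71.0% of the values under 60 lay within 0.01 of a whole multiple of a step that differed between libraries (1.0505, 0.8259 and 1.353 in Control replicates 1 to 3, 1.1103, 0.8336 and 0.9073 in KC-Tie2 replicates 1 to 3). The values were therefore taken as estimated counts divided by 1 factor per library. Whole reads were not recovered, since the other values were fractions of a step. Depth limits low values: 1 estimated count corresponds to 1 step. The table held 17550 genes (13637 protein-coding, 1332 processed pseudogenes, 1294 lncRNAs and 986 of the annotation's TEC class), 14 of them without a name. Every gene reached at least 24.78 in some library, so low genes had been removed before deposit, by a rule not given in the sources used here. Per the file headers, the second deposited table holds the authors' p-value and step-up FDR per gene. The same deposited table gives the ratio of the KC-Tie2 mean to the mean of a group headed WT and a signed fold change, which equals that ratio or minus its inverse, and the authors' model means per group. That table was counted and compared, not retested. Gene positions in the deposited table were read with the end 1 base before the listed stop. The gene annotation release and the use of strand in counting are not given in the sources used here.

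Before the data were examined, the test, the gene lists, the rule for naming genes and the alternatives were fixed, except for voom and the families and tests named in the closing section as chosen later. Values were transformed as log2(value + 1), and the 17539 genes with a mean of at least 10 over the 6 libraries were tested. The genotype effect was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust, residual degrees of freedom 4, median prior degrees of freedom 7.79). Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested, and genes with an adjusted p under 0.05 were called. Every adjusted p of a gene printed here comes from that limma model unless the authors' deposited table is named, and every adjusted p of a list comes from camera or fry. "Rose" and "fell" are used for called genes.

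Gene lists were compared with all other tested genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 49 lists with at least 3 tested members. Camera was also run with the correlation estimated from the data, under which none of the 30 lists called with the preset correlation was called. Fry was run beside it. It tests whether a set's genes move one way (3 lists called) or, in its mixed form, either way (25 lists called), and neither form compares a set with other genes. Counts of called members are given over all genes tested and adjusted over the list alone. There were 50 lists: responses (29), checks on the samples (3), cell types (12) and other tissues (6). Some genes belong to more than 1 list.

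Named genes were chosen by a fixed rule. It took the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 50 and groups that do not overlap, leaving out predicted genes, pseudogenes and immunoglobulin variable segments. It added up to 4 called members of each list with the largest absolute log2 fold change, or the 2 members with the smallest p where none was called. Tek, Havcr1, Lcn2, Xist, Ddx3y, Krt5, Krt14, Il17a, Il1b, Tnf, Il6 and Ren1 were always included. This gave 129 genes, of which 125 were tested. The genes Acads, C3, C4a, Cp, Cpt2, Ctsb, Cyp4a12b, Fga, Hdc, Kdm5d, Rps2-ps10, Slc22a5 and Stat3 fall outside the rule and were named after their values were seen.

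For called named genes with under 10 estimated counts in a genotype, the ratio of estimated counts was scaled by the library factors and given an exact binomial counting interval, chosen after the values were seen. Principal components were computed on centred, unscaled log2 values of the tested genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for the description of the tables and the figures. The alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 100, TMM scaling, quantile normalization, the replicate number as a block, eBayes without robust, library weights, each library left out in turn (counts listed in the order Control replicates 1, 2 and 3, then KC-Tie2 replicates 1, 2 and 3), other thresholds, and voom on estimated counts. Count models were not run because whole reads were not recovered.

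The limma procedure was tested on simulated data with the means, spread and library factors of these 17539 genes, in 20 simulations with 200 changed genes. It recovered 51.9% of genes changed 1.5-fold, 80.9% at 2-fold and 97.7% at 4-fold. Changed genes and the shifted list were drawn from genes with a mean of at least 50, so recovery below that mean was not measured. Of its calls 5.35% were false and 0 had the wrong sign. A shifted list of 20 genes was found in 20 of 20 simulations, and 0 of 800 unshifted lists were called. Genes were simulated independently of each other, whereas estimated correlations in the real lists were, for example, 0.756 for MHC class II and 0.774 for male-biased genes. The simulated lists therefore do not show how often camera makes false calls among correlated genes.

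Reads from near-identical genes could have been split by the counting, so values of C4b and C4a, H3c2 and H3c3, the Ces1 genes, Cyp4a12a and Cyp4a12b, Acaa1a and Acaa1b, and Hba-a1 and Hba-a2 are uncertain. Called named genes that overlap another gene are uncertain too, since the use of strand is not known. Among them are Acaa1b (with Dlec1), Cxcl16 (Zmynd15), Pfkp (Pitrm1), Fdft1 (Ctsb), Eci2 (Gm16984), Pde6a (Rps2-ps10), Car9 (Gm12454), Scnn1b (Cog7), Pkm (Gm49759), S100g (Ctps2), Slc22a12 (Nrxn2) and Slco1a6 (Gm18159 and Gm20400). Replication-dependent histone mRNAs lack poly(A) tails, so their levels after poly(A) selection are uncertain. No sample was left out.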

Results

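Bulk RNA sequencing was carried out on kidneys of KC-Tie2 mice and Control mice. KC-Tie2 is a mouse model of psoriasis in which keratinocytes, the main cells of the epidermis, carry a transgene for the receptor tyrosine kinase Tie2. Kidneys were perfused with saline, and poly(A)-selected libraries were made from total RNA. There were 3 Control and 3 KC-Tie2 libraries, and the labels used here give no sex, strain or age. The labels name separate samples without saying that each came from a separate animal, so p-values measure the spread between these samples. The deposited table held normalized counts for 17550 genes. These summed to 25378411, 24288853 and 25495455 in Control replicates 1 to 3 and to 23647811, 24604088 and 25155944 in KC-Tie2 replicates 1 to 3. The step between low values put the depth before normalization, in units of 1e+06 estimated counts, at about 24.2, 29.4 and 18.8 in the Control and 21.3, 29.5 and 27.7 in the KC-Tie2 libraries. Transcripts of the mitochondrial genome made up 12.8% to 14.2% of each sum. Gene values are given as mean ± SD of the normalized count (n = 3 per genotype). Log2 fold changes are given as the estimate ± SE on the log2(value + 1) scale, KC-Tie2 minus Control. Coordinates are those of the deposited table, on the build mm39 named in the submitters' processing notes.

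The comparison of the genotypes asked which kidney transcripts differ in mice with psoriasis-like skin disease. The 20 genes of this paragraph and the next have the 10 highest and the 10 lowest log2 fold changes among called genes with a mean of at least 50 and groups that do not overlap. Predicted genes, pseudogenes and immunoglobulin variable segments were left out. C4b, which encodes complement component C4 (ENSMUSG00000073418, chromosome 17, 34947354 to 34962856), went from 113 ± 35.2 in Control to 3738 ± 957 in KC-Tie2 kidneys, a 33.1-fold rise (log2 fold change 5.05 ± 0.30, limma adjusted p = 0.00742). Cfi, the protease that inactivates C3b and C4b (ENSMUSG00000058952, chromosome 3, 129629533 to 129668981), rose 12.8-fold, from 58.4 ± 4.08 to 773 ± 167 (log2 fold change 3.68 ± 0.16, limma adjusted p = 4.89e-07). Tfr2, transferrin receptor 2 (chromosome 5, 137568102 to 137585743), rose from 5.78 ± 2.86 to 142 ± 32.2 (21.9-fold, limma adjusted p = 0.000131), and the fibrinogen gamma chain gene Fgg (chromosome 3, 82915031 to 82922356) from 98.9 ± 36.6 to 1682 ± 771 (16.3-fold, limma adjusted p = 0.0472). In the other direction, the carboxylesterase gene Ces1g (ENSMUSG00000057074, chromosome 8, 94028997 to 94063936) fell 32.2-fold, from 881 ± 216 to 27.5 ± 12.7 (log2 fold change -5.01 ± 0.33, limma adjusted p = 0.00187). The abundant cytochrome P450 transcript Cyp4b1 (chromosome 4, 115481922 to 115504920) fell from 48038 ± 7477 to 13017 ± 4027 (3.77-fold, limma adjusted p = 0.0275).

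The other genes of the 10 highest, under the same limits, were Fgb (fibrinogen beta chain, 5.19-fold), Serpina10 (4.25-fold), the histone genes H3c2 (3.84-fold) and H3c3 (3.73-fold), Gc (vitamin D-binding protein, 3.8-fold) and Ptgds (a prostaglandin D2 synthase, 3.61-fold). Gc had one of the tightest differences, with 239 ± 37.4 in Control and 905 ± 11.3 in KC-Tie2 kidneys (limma adjusted p = 1.09e-05). The others of the 10 lowest were Hrg (histidine-rich glycoprotein, 7.28-fold), Col6a6 (5-fold), Cpe (carboxypeptidase E, 3.2-fold), Jchain (the joining chain of IgA and IgM, 3.13-fold), Pde6a (3.12-fold), Ankrd65 (3.06-fold), Spns3 (2.59-fold) and the dynein gene Dnah5 (2.55-fold). Limma adjusted p-values of these 14 genes lay between 1.09e-05 and 0.0435. Below the limit on the mean, S100a8 had 1 estimated count in the Control and 102 in the KC-Tie2 libraries, a ratio of 92.4 after scaling by library (95% counting interval 16.2 to 3690, which leaves out the spread between samples). Its limma fold of 24 depends on the added 1. S100a9 had 8 and 116 estimated counts, a ratio of 13.1 (6.45 to 31.2), and a limma fold of 9.68. Some of the 20 genes have close copies or an overlapping neighbour, which makes the share of reads counted for each uncertain: C4b has the paralog C4a (25.4 to 28.4 between the group means), H3c2 and H3c3 belong to a multigene family, and Pde6a overlaps the pseudogene Rps2-ps10 on the other strand (2912 to 3099.5). Of the 20 genes, 9, 15 and 8 kept their call without Control replicate 1, 2 and 3, and 9, 9 and 20 without KC-Tie2 replicate 1, 2 and 3. Tfr2, Cfi, Gc and Ces1g kept it in all 6 of these fits.

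**Figure D1:**
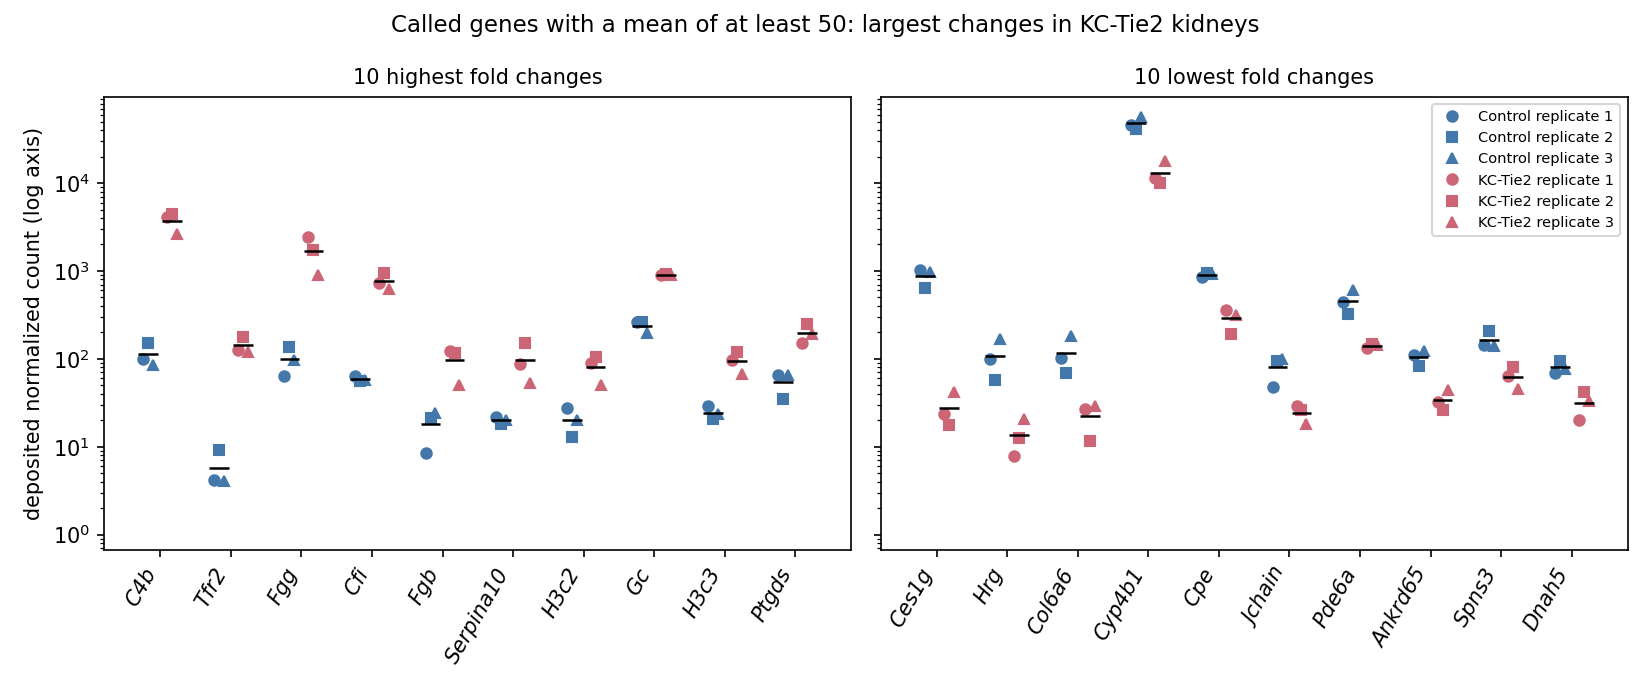
Deposited normalized counts (log axis) of the 10 genes with the highest and the 10 with the lowest log2 fold changes among called genes with a mean of at least 50 and groups that do not overlap, without predicted genes, pseudogenes and immunoglobulin variable segments. Each point is 1 library and each bar a group mean (n = 3). The Control and KC-Tie2 libraries do not overlap at any of the 20 genes, and KC-Tie2 replicate 3 is often the KC-Tie2 library nearest to the Control libraries, as for C4b (2659 against 4069.6 and 4484).

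Across the 17539 genes tested, 297 differed between the genotypes at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 150 higher and 147 lower in KC-Tie2 kidneys. Of these, 38 were higher and 29 lower by at least 2-fold, and 277 of the 297 were protein-coding. At an unadjusted p under 0.05 there were 2691 genes, 1328 higher and 1363 lower. The 3 KC-Tie2 libraries lay entirely above or below the 3 Control libraries at all 297 genes and at 20% of all genes tested, where chance gives 10%. The first principal component held 34.3% of the variance and separated the genotypes, with scores of -25.2, -10.4 and -27.6 for Control replicates 1 to 3 and 26.9, 29.4 and 6.93 for KC-Tie2 replicates 1 to 3. Of 49 gene lists tested with camera's preset correlation, 22 were higher and 8 lower in KC-Tie2 kidneys, and 0 of these 30 were called with an estimated correlation. Spearman correlations between libraries, taken across genes, were 0.989 to 0.990 within a genotype and 0.981 to 0.991 between genotypes, so the genotype difference was small against what the kidneys shared. KC-Tie2 replicate 3 was the KC-Tie2 library closest to the Control mean at 228 of the 297 genes, and Control replicate 2 was the Control library closest to the KC-Tie2 mean at 181, where equal shares would be 99. The number of called genes was 51, 530 and 54 without Control replicate 1, 2 and 3 and 69, 48 and 682 without KC-Tie2 replicate 1, 2 and 3.

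Genes of the acute phase response, plasma proteins and regulators induced by interleukin-6 and related cytokines, were higher as a group. All 22 tested members had a log2 fold change above 0, and 6 rose. These were C4b, Fgg and Fgb, the cytokine feedback inhibitor Socs3 (48.5 ± 9.1 to 111 ± 31, limma adjusted p = 0.0435), the copper carrier Cp (log2 fold change 0.90 ± 0.14) and the transcription factor Stat3 (0.87 ± 0.11). In all 14 rose adjusted over the list alone. The acute phase list had a median log2 fold change of 0.88 (camera adjusted p = 2.53e-16, adjusted p = 0.403 with an estimated correlation), and fry, which tests whether its genes move one way, gave an adjusted p of 0.0418. Fga, the remaining fibrinogen chain, had 462 ± 79.8 in Control and 2604 ± 989.7 in KC-Tie2 kidneys (limma adjusted p = 0.0594). Lcn2, a marker of neutrophils and injured tubules, had 45.3 ± 19 and 118 ± 48.6 (limma adjusted p = 0.134). The count of risen members was 0, 7 and 2 without Control replicate 1, 2 and 3 and 2, 2 and 10 without KC-Tie2 replicate 1, 2 and 3. It was 6, 7, 8 and 3 with the replicate block, eBayes without robust, library weights and voom. The list alone gave 12, 15, 8, 12, 13 and 10 in the order of left-out libraries.

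Complement genes were also higher. Of 18 tested, 5 rose and none fell, and 8 rose and 1 fell adjusted over the list alone. The complement list had a median log2 fold change of 0.45 (camera adjusted p = 2.74e-06, adjusted p = 0.403 with an estimated correlation), with an adjusted p of 0.0418 by fry. Besides C4b and Cfi, the genes that rose were the C1q chains that start the classical pathway: C1qa (132 ± 11.7 to 254 ± 5.79, limma adjusted p = 0.00742), C1qb (1.69-fold) and C1qc (1.7-fold). C3, the central component, had 382 ± 115 in Control and 1684 ± 664 in KC-Tie2 kidneys (limma adjusted p = 0.148). The count of risen complement genes was 2, 5 and 3 without Control replicate 1, 2 and 3 and 3, 3 and 6 without KC-Tie2 replicate 1, 2 and 3. It was 6, 5, 5 and 4 with the replicate block, eBayes without robust, library weights and voom, and 5, 7, 5, 5, 5 and 10 over the list alone in the order of left-out libraries. In the fit with the replicate block and in that without Control replicate 2, 1 complement gene fell.

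Transcripts of myeloid cells were higher. Of 18 neutrophil markers only 4 were tested. All 4 were above 0, 3 rose, and 4 rose adjusted over the list alone. S100a8 and S100a9 reached the mean of at least 10 only through the KC-Tie2 libraries, so the filter partly set their direction. S100a8, a subunit of calprotectin, was at 0, 0.826 and 0 in the Control libraries and at 42.2, 41.7 and 12.7 in the KC-Tie2 libraries (limma adjusted p = 0.0217). Its partner S100a9 went from 2.63 ± 1.54 to 37.9 ± 24.9 (limma adjusted p = 0.036), and the granulocyte colony-stimulating factor receptor Csf3r from 10.2 ± 2.58 to 37.2 ± 4.75 (limma adjusted p = 0.0369). The neutrophil list had a median log2 fold change of 2.53 (camera adjusted p = 1.36e-05, adjusted p = 0.403 with an estimated correlation), with an adjusted p of 0.0418 by fry. Haemoglobin genes, a measure of residual blood, summed to 1837, 2155 and 1422 in the Control and 4956, 919 and 3926 in the KC-Tie2 libraries. Of 23 macrophage and dendritic cell markers, 22 were above 0 and 3 rose, the C1q genes C1qa, C1qb and C1qc. A further count, adjusted over the list alone, gave 8 risen. The macrophage list had a median log2 fold change of 0.53 (camera adjusted p = 3.71e-07, adjusted p = 0.444 with an estimated correlation). With Control replicates 1, 2 and 3 and KC-Tie2 replicates 1, 2 and 3 left out in turn, risen members numbered 0, 3, 0, 0, 0 and 3 for neutrophils and 1, 3, 1, 1, 1 and 8 for macrophages. The limit of a mean of at least 100 left only 1 neutrophil marker tested, Hdc, and it was not called. Risen macrophage and dendritic cell markers numbered 3, 2, 3 and 2 with the replicate block, eBayes without robust, library weights and voom, and neutrophil markers 3, 3, 3 and 2. Macrophage markers risen over the list alone numbered 3, 12, 4, 3, 3 and 11 in the order of left-out libraries.

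Of 10 tested B and plasma cell markers 3 fell, over all genes and adjusted over the list alone. They were Jchain, the IgA heavy chain Igha (287 ± 74.6 to 121 ± 11.9, limma adjusted p = 0.0128) and the kappa light chain Igkc (164 ± 50.4 to 74.9 ± 16.9, limma adjusted p = 0.0489). The B and plasma cell list had a median log2 fold change of -0.013 (camera adjusted p = 0.0897, adjusted p = 0.588 with an estimated correlation). It passed camera at a mean of at least 100 (0.0491), without Control replicate 1 (0.0188) and without KC-Tie2 replicate 1 (0.0494), within a range of 0.0188 to 0.847 over all alternatives with the preset correlation. Fallen members numbered 2, 1 and 0 without Control replicate 1, 2 and 3 and 1, 0 and 3 without KC-Tie2 replicate 1, 2 and 3. There were 3, 2, 3 and 1 with the replicate block, eBayes without robust, library weights and voom. Among 6 tested T and NK cell markers no gene was called, over all genes or the list alone (median log2 fold change -0.071, camera adjusted p = 0.521, adjusted p = 0.761 with an estimated correlation, limma unadjusted p under 0.05 at 1 member). Cd4 had 19.8 ± 5.73 and 9.03 ± 3.99.

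Among 31 cytokines that drive psoriasis and their target genes, 10 were tested and 3 rose. These were S100a8, S100a9 and Nfkbiz, a transcriptional regulator induced by interleukin-17 (244 ± 33.1 to 482 ± 123, limma adjusted p = 0.0471). S100a8 and S100a9 reached the mean of at least 10 only through the KC-Tie2 libraries, so the filter partly set their direction here too. There were 4 risen adjusted over the list alone. The psoriasis list had a median log2 fold change of 0.90 (camera adjusted p = 7.34e-05, adjusted p = 0.403 with an estimated correlation). Its camera call was lost at a mean of at least 100 (0.0947), within a range of 2.45e-05 to 0.0947 over all alternatives with the preset correlation. At that limit 5 of its genes were tested, 1 rose and the median was 0.13. Il1b was at 11.3 ± 7.39 in Control and 22.2 ± 9.49 in KC-Tie2 kidneys (limma adjusted p = 0.428), and Il17a, Il6 and Tnf are not among the genes of the table analysed here. NF-kB targets had 2 risen members of 18, also 2 adjusted over the list alone: the adhesion molecule Icam1 (329 ± 37.6 to 555 ± 113, limma adjusted p = 0.036) and the chemokine Cxcl16 (1.44-fold). The NF-kB list had a median log2 fold change of 0.14 (camera adjusted p = 0.00152, adjusted p = 0.537 with an estimated correlation). That call was lost without KC-Tie2 replicate 1 (0.0529), within a range of 7.01e-05 to 0.0529 over all alternatives with the preset correlation. Risen members with Control replicates 1, 2 and 3 and KC-Tie2 replicates 1, 2 and 3 left out in turn numbered 0, 4, 0, 0, 0 and 4 in the psoriasis list and 0, 2, 0, 0, 0 and 4 in the NF-kB list. NF-kB targets risen over the list alone numbered 2, 4, 2, 2, 2 and 7 in that order. Over all genes, risen members of the psoriasis list numbered 4, 3, 3 and 1 with the replicate block, eBayes without robust, library weights and voom, and in the NF-kB list 3, 1, 2 and 0.

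Interferon and antigen presentation genes were higher as lists, without a single member called over all genes. Of 35 interferon response genes 29 were above 0, and 2 rose adjusted over the list alone. The interferon list had a median log2 fold change of 0.26 (camera adjusted p = 5.59e-05, adjusted p = 0.406 with an estimated correlation, limma unadjusted p under 0.05 at 12 members), Parp14 having 666 ± 97.7 and 908 ± 69.9 (limma adjusted p = 0.0594 over all genes). MHC class I and its loading genes had 14 of 15 above 0 and 4 risen adjusted over the list alone. The class I list had a median log2 fold change of 0.25 (camera adjusted p = 4.65e-05, adjusted p = 0.444 with an estimated correlation, limma unadjusted p under 0.05 at 7 members), with H2-D1 at 3029 ± 180.1 and 3784 ± 339.8. All 8 MHC class II genes were above 0, and 7 rose adjusted over the list alone. The class II list had a median log2 fold change of 0.62 (camera adjusted p = 1.36e-06, adjusted p = 0.406 with an estimated correlation, limma unadjusted p under 0.05 at 7 members), with H2-DMb1 at 136 ± 36.5 and 351 ± 153 (limma adjusted p = 0.152 over all genes). Over all genes, the interferon and class I lists each had 3 risen members without Control replicate 2 and 3 without KC-Tie2 replicate 3. With the replicate block, eBayes without robust, library weights and voom, risen members over all genes numbered 1, 0, 2 and 0 in the interferon list, 3, 0, 3 and 0 in the class I list and 6, 0, 0 and 0 in the class II list. Adjusted over the list alone, risen class II genes numbered 0, 7 and 0 without Control replicate 1, 2 and 3 and 2, 4 and 8 without KC-Tie2 replicate 1, 2 and 3. In the same order, class I genes numbered 0, 7, 0, 1, 0 and 5, and interferon genes 0, 6, 0, 0, 0 and 4.

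Genes of fatty acid oxidation, the main fuel pathway of the proximal tubule, were lower. Of 31 tested 27 were below 0, 6 fell and none rose, and 17 fell adjusted over the list alone. Among the genes that fell were the peroxisomal enzymes Acaa1b (5178 ± 668 to 3162 ± 391, limma adjusted p = 0.0163), Ehhadh (1.59-fold) and Eci2 (1.35-fold). The mitochondrial enzymes Cpt2 (1.34-fold) and Acads (1.28-fold) fell too. The fatty acid oxidation list had a median log2 fold change of -0.27 (camera adjusted p = 2.69e-11, adjusted p = 0.444 with an estimated correlation). Organic ion and drug transporters, which secrete and reabsorb small molecules in the proximal tubule, were lower as well. Of 25 tested 21 were below 0, 5 fell and 14 fell adjusted over the list alone. Among them were the urate transporter Slc22a12 (27082 ± 2375 to 18351 ± 2509.7, limma adjusted p = 0.0228), the multidrug extruder Slc47a1 (1.4-fold) and the carnitine transporter Slc22a5 (1.3-fold). The transporter list had a median log2 fold change of -0.33 (camera adjusted p = 5.03e-10, adjusted p = 0.403 with an estimated correlation). Proximal tubule markers had 2 fallen members of 23. These were Acsm2 (86742 ± 10666 to 58160.1 ± 9045, limma adjusted p = 0.0435) and the arginine synthesis enzyme Ass1 (19075 ± 1713 to 12998 ± 1346, limma adjusted p = 0.0172). There were 3 risen and 9 fallen adjusted over the list alone. The proximal tubule list had a median log2 fold change of -0.20 (camera adjusted p = 0.000244, adjusted p = 0.498 with an estimated correlation). Camera no longer called it after quantile normalization (0.0971), within a range of 3.79e-05 to 0.0971 over all alternatives with the preset correlation. Fallen members with Control replicates 1, 2 and 3 and KC-Tie2 replicates 1, 2 and 3 left out in turn numbered 0, 11, 1, 0, 0 and 9 for fatty acid oxidation, 0, 7, 0, 0, 0 and 6 for transporters and 0, 4, 0, 0, 0 and 5 for the proximal tubule. Those counts were 7, 5, 8 and 4 for fatty acid oxidation, 11, 7, 5 and 5 for transporters and 7, 2, 3 and 1 for the proximal tubule with the replicate block, eBayes without robust, library weights and voom. Fallen over the list alone, in the order of left-out libraries, were 8, 21, 10, 10, 11 and 17 for fatty acid oxidation, 10, 13, 7, 8, 10 and 16 for transporters and 5, 6, 5, 4, 4 and 12 for the proximal tubule, whose risen ones numbered 1, 0, 1, 2, 0 and 2.

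Cholesterol synthesis genes were higher, with 7 of 22 risen, none fallen and 10 risen adjusted over the list alone. Among the risen genes were the pathway enzymes Pmvk (134 ± 9.92 to 239 ± 41.9, limma adjusted p = 0.0278), Msmo1 (1.59-fold) and Fdft1 (1.54-fold). Fdft1 overlaps Ctsb on the other strand (8870.2 to 11249 between the means), so its level is uncertain. The cholesterol list had a median log2 fold change of 0.31 (camera adjusted p = 8.4e-07, adjusted p = 0.403 with an estimated correlation). In glycolysis and gluconeogenesis 4 of 23 rose, and 5 adjusted over the list alone. The called genes were the glycolytic enzymes Pfkp (1206 ± 85 to 1820.3 ± 305, limma adjusted p = 0.0339), Pkm (1.39-fold), Pfkl (1.32-fold) and Hk1 (1.31-fold). The gluconeogenic gene Pck1 had 55399.9 ± 18260.0 in Control and 27443 ± 12441 in KC-Tie2 kidneys (limma adjusted p = 0.339). The glycolysis list had a median log2 fold change of 0.071 (camera adjusted p = 0.0147, adjusted p = 0.563 with an estimated correlation). Camera no longer called it without Control replicate 2 (0.18) and without KC-Tie2 replicate 2 (0.0949), within a range of 0.000234 to 0.18 over all alternatives with the preset correlation. Lipogenesis genes had 1 fallen of 15, the malic enzyme Me1 (8792 ± 653 to 6234 ± 983, limma adjusted p = 0.0435). The lipogenesis list had 1 risen and 3 fallen adjusted over the list alone, and had a median log2 fold change of 0.07 (camera adjusted p = 0.935, adjusted p = 0.976 with an estimated correlation). With Control replicates 1, 2 and 3 and KC-Tie2 replicates 1, 2 and 3 left out in turn, risen members numbered 0, 7, 0, 3, 0 and 6 for cholesterol synthesis and 0, 4, 0, 0, 0 and 4 for glycolysis. Fallen lipogenesis genes numbered 0, 2, 0, 0, 0 and 1 in the same order. Counts with the replicate block, eBayes without robust, library weights and voom were 9, 5, 9 and 6 risen for cholesterol synthesis, 4, 4, 4 and 4 risen for glycolysis and 1, 0, 2 and 0 fallen for lipogenesis. The replicate block and the fit without Control replicate 2 each also had 1 risen lipogenesis gene. Lipogenesis genes over the list alone numbered 2, 4, 0, 0, 0 and 2 risen and 2, 4, 0, 2, 1 and 3 fallen in the order of left-out libraries.

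Male-biased kidney genes, which are higher in male than in female mouse kidney, were lower in KC-Tie2 kidneys as a list. All 16 had a log2 fold change below 0, none was called over all genes tested in the limma fit used throughout, and 12 fell adjusted over the list alone. The male-biased list had a median log2 fold change of -0.86 (camera adjusted p = 3.96e-15, adjusted p = 0.403 with an estimated correlation, limma unadjusted p under 0.05 at 14 members). Cyp4a12a, a fatty acid hydroxylase, had 2043 ± 671 in Control and 169.9 ± 95.1 in KC-Tie2 kidneys (limma adjusted p = 0.0719), with an uncertain share of reads from its close copy Cyp4a12b. The groups did not overlap at 11 of the 16 genes, against 20% of all genes tested, where chance gives 10%. The median member stood at 102%, 79.6% and 118% of its Control mean in Control replicates 1 to 3 and at 45.4%, 51.0% and 70.4% in KC-Tie2 replicates 1 to 3. Fallen male-biased genes over all genes numbered 0, 3 and 0 without Control replicate 1, 2 and 3 and 0, 0 and 8 without KC-Tie2 replicate 1, 2 and 3. With the replicate block, eBayes without robust, library weights and voom they numbered 12, 7, 2 and 0, so the calls of single members depend on the model. They numbered 0, 13, 5, 0, 0 and 14 in the same order when adjusted over the list alone. Female-biased genes had 1 risen and 2 fallen of 14, the same adjusted over the list alone. Slc22a29 rose (107 ± 18 to 226 ± 63.2, limma adjusted p = 0.0297), and Slco1a6 (1.33-fold) and Acsm2 fell. The female-biased list had a median log2 fold change of 0.16 (camera adjusted p = 0.126, adjusted p = 0.627 with an estimated correlation). It passed camera with the replicate block (0.0371), without Control replicate 1 (0.0473) and without KC-Tie2 replicate 1 (0.00445), within a range of 0.00445 to 0.472 over all alternatives with the preset correlation. With single libraries left out in that order, 0, 0, 0, 1, 0 and 1 of its genes rose and 0, 2, 0, 0, 0 and 2 fell. Female-biased genes with the replicate block, eBayes without robust, library weights and voom numbered 3, 2, 1 and 0 risen and 2, 1, 2 and 1 fallen.

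**Figure D2:**
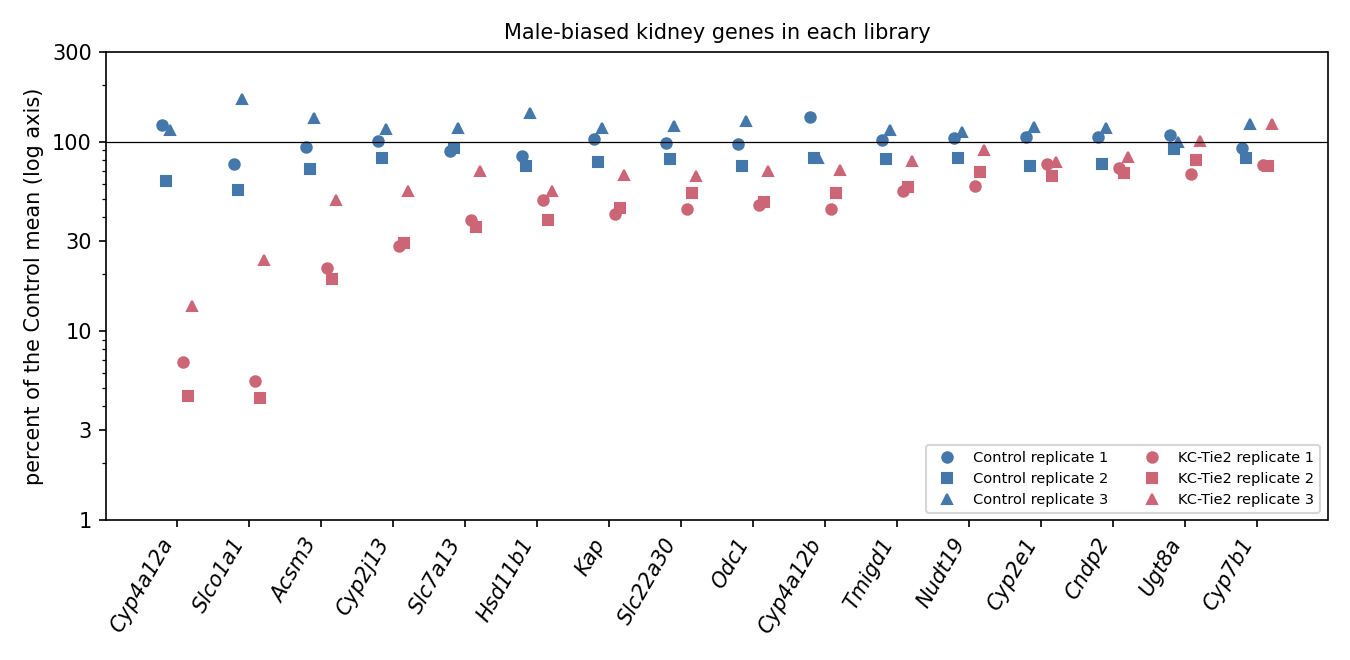
Level of each of the 16 male-biased kidney genes in each library, as a percent of the gene's Control mean (log axis, each point 1 library). The KC-Tie2 libraries lie below every Control library at 11 of the 16 genes, and KC-Tie2 replicate 3 is the highest of the KC-Tie2 libraries at each of the 16, with a median of 70.4% against 45.4% and 51.0%.

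All 6 libraries carried Y-linked transcripts. The summed level of Ddx3y, Kdm5d, Uty and Eif2s3y was 105.5%, 93.2% and 101% of the Control mean in Control replicates 1 to 3 and 80.4%, 86.7% and 93.9% in KC-Tie2 replicates 1 to 3. Ddx3y had 925 ± 74.8 and 799 ± 133 (limma adjusted p = 0.4). Xist, the RNA of the inactive X chromosome, was at 98.4, 89.3 and 415 in the Control and 38.2, 25.6 and 241 in the KC-Tie2 libraries. All 5 tested members of the X inactivation and Y-linked list were below 0, none was called over all genes and 1 fell adjusted over the list alone. The list had a median log2 fold change of -0.22 (camera adjusted p = 0.00643, adjusted p = 0.469 with an estimated correlation, limma unadjusted p under 0.05 at 2 members). Members fallen over the list alone numbered 0, 2, 0, 0, 0 and 2 in the order of left-out libraries. Over all genes 1 member fell without Control replicate 2, and 1 with the replicate block.

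Calb1, the calcium buffer calbindin-D28k, went from 6809 ± 794 to 12367 ± 1819.5 (limma adjusted p = 0.0106), and S100g, calbindin-D9k, from 3275 ± 170.0 to 6496 ± 859.8 (limma adjusted p = 0.000548). The apical calcium channel Trpv5 went from 438 ± 71.3 to 753 ± 84.6 (limma adjusted p = 0.0158). Calb1 and S100g kept their call without any single library, and Trpv5 lost it without KC-Tie2 replicates 1 and 2. In the same list, of mineral and vitamin D handling, the vitamin D receptor Vdr fell (7506 ± 611 to 5654 ± 337, limma adjusted p = 0.0313). Of 19 genes 3 rose and 1 fell, 5 and 1 adjusted over the list alone. The mineral list had a median log2 fold change of 0.044 (camera adjusted p = 0.285, adjusted p = 0.757 with an estimated correlation). Leaving out Control replicates 1, 2 and 3 and KC-Tie2 replicates 1, 2 and 3 in turn, 3, 4, 3, 2, 2 and 4 of its genes rose and 0, 1, 0, 0, 0 and 1 fell. Mineral genes with the replicate block, eBayes without robust, library weights and voom numbered 4, 3, 4 and 3 risen and 1, 1, 1 and 1 fallen.

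Distal convoluted tubule markers had 2 risen of 9, Calb1 and the magnesium channel Trpm6 (1.29-fold), and 4 adjusted over the list alone. That list had a median log2 fold change of 0.22 (camera adjusted p = 0.000167, adjusted p = 0.406 with an estimated correlation). In collecting duct principal cells all 13 markers were above 0, and the sodium channel subunits Scnn1a (1.31-fold) and Scnn1b (1.34-fold) rose. Adjusted over the list alone 8 rose, and the principal cell list had a median log2 fold change of 0.28 (camera adjusted p = 2.47e-07, adjusted p = 0.403 with an estimated correlation). No member passed over all genes in the lists of intercalated cells, loop of Henle and podocytes. Adjusted over the list alone, 9 rose and 1 fell of 15 intercalated cell markers, such as the ammonia channel Rhcg (1713 to 2093 between the means). The intercalated cell list had a median log2 fold change of 0.26 (camera adjusted p = 8.51e-05, adjusted p = 0.444 with an estimated correlation, limma unadjusted p under 0.05 at 11 members). In the loop of Henle 4 of 14 rose adjusted over the list alone, with the urea transporter Slc14a2 at 1313 and 2387. The loop of Henle list had a median log2 fold change of 0.21 (camera adjusted p = 0.000855, adjusted p = 0.403 with an estimated correlation, limma unadjusted p under 0.05 at 5 members). Of 15 podocyte markers 4 rose adjusted over the list alone. The podocyte list had a median log2 fold change of 0.26 (camera adjusted p = 7.42e-05, adjusted p = 0.498 with an estimated correlation, limma unadjusted p under 0.05 at 6 members). With Control replicates 1, 2 and 3 and KC-Tie2 replicates 1, 2 and 3 left out in turn, risen members numbered 1, 2, 1, 1, 1 and 4 for the distal convoluted tubule and 0, 3, 0, 0, 0 and 4 for principal cells. In the same order they numbered 0, 2, 0, 0, 0 and 5 for intercalated cells, 0, 2, 0, 0, 0 and 2 for the loop of Henle and 0, 0, 0, 0, 0 and 4 for podocytes. Risen members with the replicate block, eBayes without robust, library weights and voom numbered 3, 2, 4 and 2 for the distal convoluted tubule and 3, 1, 3 and 1 for principal cells. They numbered 1, 0, 1 and 0 for intercalated cells, 2, 1, 1 and 0 for the loop of Henle and 1, 0, 0 and 0 for podocytes with the same alternatives. Adjusted over the list alone, risen members with Control replicates 1, 2 and 3 and KC-Tie2 replicates 1, 2 and 3 left out in turn numbered 5, 10, 7, 5, 4 and 7 for principal cells, 8, 10, 0, 0, 0 and 8 for intercalated cells, 0, 3, 0, 0, 0 and 4 for the loop of Henle and 4, 0, 0, 0, 0 and 9 for podocytes. The intercalated cell list alone gave 1 fallen marker without Control replicate 1, 1 without Control replicate 2 and 0 in the other 4 fits.

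**Figure D3:**
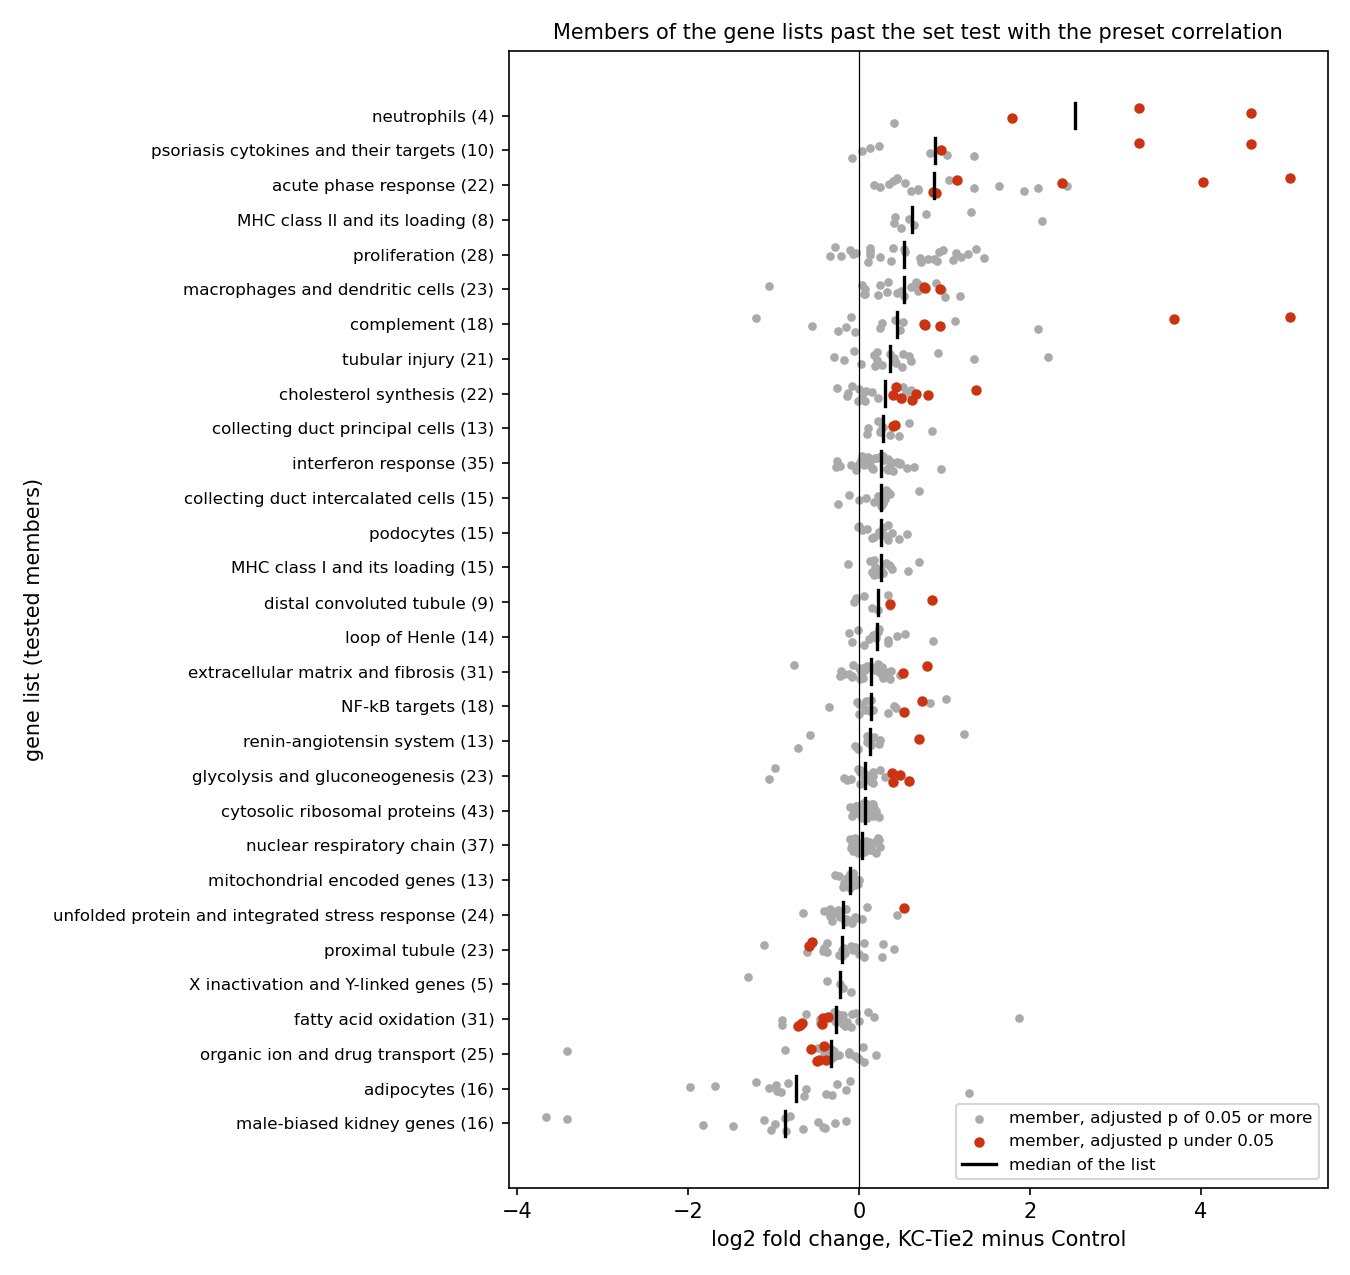
Log2 fold change (KC-Tie2 minus Control) of each tested member of the 30 gene lists that passed camera with the preset correlation, each point 1 gene and each bar the list's median, with the number of tested members in brackets. The medians run from -0.86 for male-biased kidney genes to 2.53 for neutrophils, and none of the 30 lists passes with an estimated correlation.

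Angiotensinogen, Agt, the precursor of angiotensin, rose from 1198 ± 130.2 to 1942 ± 200.4 (limma adjusted p = 0.00742) and kept its call without any single library. Renin, Ren1, had 763 ± 181 in Control and 1913 ± 982 in KC-Tie2 kidneys (limma adjusted p = 0.289), with 1347, 3047 and 1345 in KC-Tie2 replicates 1 to 3. The renin-angiotensin list had 1 risen of 13, and 2 risen and 1 fallen adjusted over the list alone. It had a median log2 fold change of 0.13 (camera adjusted p = 0.0298, adjusted p = 0.575 with an estimated correlation). Its camera call was lost with the replicate block (0.0593), without Control replicate 2 (0.272), without KC-Tie2 replicate 2 (0.0795) and without KC-Tie2 replicate 3 (0.065), within a range of 0.00233 to 0.272 over all alternatives with the preset correlation. Risen members over the list alone numbered 1, 1, 1, 1, 2 and 2 in the order of left-out libraries. Over all genes 1 member fell with the replicate block, after quantile normalization, with eBayes without robust, with library weights, and without Control replicate 2 or KC-Tie2 replicate 3.

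Tubular injury markers were higher as a list, with none called over all genes. Of 21 tested 18 were above 0, and 5 rose and 1 fell adjusted over the list alone. The injury list had a median log2 fold change of 0.37 (camera adjusted p = 0.000264, adjusted p = 0.474 with an estimated correlation, limma unadjusted p under 0.05 at 7 members). The 2 members with the smallest p were Krt7 (1919 ± 264 and 2575 ± 216, limma adjusted p = 0.0649) and Spp1 (12096 ± 1735 and 58725 ± 22693, limma adjusted p = 0.0681). In the authors' deposited table Krt7 had an FDR of 0.0068 and Spp1 of 1.49e-08. Havcr1, the injury marker KIM-1, had 24.2 ± 3.75 in Control and 62.6 ± 57.5 in KC-Tie2 kidneys (limma adjusted p = 0.56). Its levels in KC-Tie2 replicates 1 to 3 were 42.2, 128 and 18.1. Among extracellular matrix and fibrosis genes 2 of 31 rose, also 2 adjusted over the list alone. They were Tgfbi, a matrix protein induced by TGF-beta (202 ± 25.3 to 353 ± 71.5, limma adjusted p = 0.0313), and fibronectin, Fn1 (1375 ± 131 to 1971 ± 174, limma adjusted p = 0.0159). The matrix list had a median log2 fold change of 0.14 (camera adjusted p = 0.00275, adjusted p = 0.627 with an estimated correlation). Its call was lost without Control replicate 3 (0.598) and without KC-Tie2 replicate 1 (0.176), within a range of 3.27e-06 to 0.598 over all alternatives with the preset correlation. In these 2 fits its median turned negative (-0.034 and -0.037), while camera's direction stayed upward. Of 28 proliferation genes 22 were above 0 and none was called, over all genes or the list alone. The proliferation list had a median log2 fold change of 0.53 (camera adjusted p = 0.000345, adjusted p = 0.498 with an estimated correlation, limma unadjusted p under 0.05 at 8 members). Its call was lost at a mean of at least 100 (0.76), within a range of 7.13e-07 to 0.76 over all alternatives with the preset correlation. Risen members with Control replicates 1, 2 and 3 and KC-Tie2 replicates 1, 2 and 3 left out in turn numbered 0, 3, 0, 0, 0 and 4 for tubular injury, 0, 4, 0, 0, 0 and 3 for matrix and 0, 0, 0, 0, 0 and 6 for proliferation. With the replicate block, eBayes without robust, library weights and voom they numbered 4, 1, 2 and 0 for tubular injury and 3, 2, 2 and 1 for matrix. Injury markers risen over the list alone numbered 0, 6, 0, 0, 1 and 7 in that order of left-out libraries, and matrix genes 2, 12, 2, 2, 2 and 7. Over the list alone 9 proliferation genes rose without KC-Tie2 replicate 3.

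Tek itself, which encodes Tie2, was at 1048 ± 50.9 in Control and 948 ± 24.8 in KC-Tie2 kidneys (log2 fold change -0.14 ± 0.07, limma adjusted p = 0.361). Kidney endothelium expresses Tek and the transgene is directed to skin, so this level does not check the labels. The Tie2 receptor axis had no called member of 6, over all genes or the list alone. That list had a median log2 fold change of -0.022 (camera adjusted p = 0.876, adjusted p = 0.95 with an estimated correlation, limma unadjusted p under 0.05 at 0 members), and its mean of 0.025 differs in sign from its median and from camera's downward direction. Among 14 endothelial activation genes Icam1 rose and Esm1 fell (402 ± 42.5 to 249 ± 32.6, limma adjusted p = 0.021). There were 1 risen and 2 fallen adjusted over the list alone. That list had a median log2 fold change of -0.0031 (camera adjusted p = 0.986, adjusted p = 0.991 with an estimated correlation), and its median and its mean of -0.023 differ in sign from camera's upward direction. Icam1 and Esm1 lost their calls without Control replicate 1, Control replicate 3, KC-Tie2 replicate 1 and KC-Tie2 replicate 2, each of which left 0 called members. The list alone gave 1, 4, 1, 1, 1 and 2 risen and 1, 3, 2, 2, 2 and 3 fallen in the order of left-out libraries. No endothelial cell marker of 21 was called, over all genes or the list alone (median log2 fold change 0.028, camera adjusted p = 0.695, adjusted p = 0.851 with an estimated correlation, limma unadjusted p under 0.05 at 1 member). The same was true of 21 fibroblast and perivascular markers (median log2 fold change 0.054, camera adjusted p = 0.263, adjusted p = 0.848 with an estimated correlation, limma unadjusted p under 0.05 at 2 members). Those passed camera without Control replicate 2 (0.0258) and without KC-Tie2 replicate 2 (0.0239), within a range of 0.0239 to 0.514 over all alternatives with the preset correlation. Over the list alone 1 of them rose with eBayes without robust and 1 without KC-Tie2 replicate 2, and 1 Tie2 axis gene without Control replicate 2.

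Energy and translation genes shifted by little, and no member of the next 3 lists was called, over all genes or adjusted over the list alone. The 13 mitochondrially encoded genes were all below 0, and the list had a median log2 fold change of -0.11 (camera adjusted p = 0.043, adjusted p = 0.695 with an estimated correlation, limma unadjusted p under 0.05 at 1 member). For example, mt-Nd5 had 271320.0 ± 18169 and 231494 ± 26789. The call was lost at a mean of at least 100 (0.0554), after quantile normalization (0.949), with the replicate block (0.0694), with library weights (0.0514), without Control replicate 1 (0.131), without Control replicate 3 (0.181) and without KC-Tie2 replicate 1 (0.472), within a range of 0.0106 to 0.949 over all alternatives with the preset correlation. After quantile normalization the direction also turned. The 37 nuclear respiratory chain genes had a median log2 fold change of 0.037 (camera adjusted p = 0.0228, adjusted p = 0.757 with an estimated correlation, limma unadjusted p under 0.05 at 7 members). That call was lost without Control replicate 2 (0.991), without KC-Tie2 replicate 2 (0.216) and without KC-Tie2 replicate 3 (0.144), within a range of 6.47e-05 to 0.991 over all alternatives with the preset correlation, and the median was -0.027 without Control replicate 2. Quantile normalization gave 1 risen member over all genes and 8 over the list alone, and library weights 4 over the list alone. The 43 cytosolic ribosomal protein genes had a median log2 fold change of 0.065 (camera adjusted p = 0.00605, adjusted p = 0.575 with an estimated correlation, limma unadjusted p under 0.05 at 6 members). That call was lost without Control replicate 2 (0.0726), within a range of 0.000137 to 0.0726 over all alternatives with the preset correlation.

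The hypoxia target Car9 fell from 206 ± 30.1 to 101 ± 15.8 (limma adjusted p = 0.0158), the 1 call among 17 hypoxia genes, over the list alone too. The hypoxia list had a median log2 fold change of -0.014 (camera adjusted p = 0.845, adjusted p = 0.851 with an estimated correlation). Ppp1r15a, which reverses the integrated stress response, rose from 299 ± 8.96 to 430.1 ± 26.3 (limma adjusted p = 0.0228). Of the 24 genes in its list, of the unfolded protein and integrated stress response, 20 were below 0, and 1 rose and 2 fell adjusted over the list alone. That list had a median log2 fold change of -0.19 (camera adjusted p = 0.00468, adjusted p = 0.627 with an estimated correlation), with camera's direction downward, opposite to Ppp1r15a. Its call was lost without Control replicate 1 (0.11) and without KC-Tie2 replicate 2 (0.0766), within a range of 8.95e-06 to 0.11 over all alternatives with the preset correlation. Its fallen members over all genes numbered 0, 2, 0, 0, 0 and 2 without Control replicates 1, 2 and 3 and KC-Tie2 replicates 1, 2 and 3, and 2, 0, 2 and 0 with the replicate block, eBayes without robust, library weights and voom. The list alone gave 0, 5, 0, 0, 0 and 11 in the order of left-out libraries. Among 18 oxidative stress genes the secreted glutathione peroxidase Gpx3 rose (295120.0 ± 27799 to 443232 ± 24120.0, limma adjusted p = 0.0154) and catalase, Cat, fell (18636 ± 896 to 14146 ± 1454, limma adjusted p = 0.0437). Adjusted over the list alone 1 rose and 2 fell. The oxidative stress list had a median log2 fold change of -0.07 (camera adjusted p = 0.104, adjusted p = 0.627 with an estimated correlation), and passed camera without Control replicate 3 (0.0115) and without KC-Tie2 replicate 3 (0.0179), within a range of 0.0115 to 0.646 over all alternatives with the preset correlation. These 4 genes lost their calls without Control replicate 1, Control replicate 3 and KC-Tie2 replicate 2. Ppp1r15a and Cat also lost them without KC-Tie2 replicate 1. Oxidative stress genes fallen over the list alone numbered 2, 2, 1, 1, 1 and 4 in the order of left-out libraries. The oxidative stress list had 1, 0, 1 and 1 risen and 2, 0, 1 and 1 fallen members with the replicate block, eBayes without robust, library weights and voom.

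No gene was called over all genes in the heat shock, immediate early, circadian or glucocorticoid lists. Of 16 heat shock genes 11 were below 0 and 4 fell adjusted over the list alone, with Hsp90ab1 at 24654 ± 1262 and 19288 ± 2619. The heat shock list had a median log2 fold change of -0.17 (camera adjusted p = 0.0509, adjusted p = 0.627 with an estimated correlation, limma unadjusted p under 0.05 at 7 members). It passed camera at a mean of at least 100 (0.0278), with TMM scaling (0.043), with library weights (0.019), without Control replicate 3 (0.00458), without KC-Tie2 replicate 3 (0.000353) and with voom (0.0376), within a range of 0.000353 to 0.458 over all alternatives with the preset correlation. Of 16 immediate early genes 2 rose adjusted over the list alone, and the list had a median log2 fold change of 0.12 (camera adjusted p = 0.24, adjusted p = 0.629 with an estimated correlation, limma unadjusted p under 0.05 at 6 members). Of 19 circadian genes 1 rose and 1 fell adjusted over the list alone. The circadian list had a median log2 fold change of -0.18 (camera adjusted p = 0.198, adjusted p = 0.629 with an estimated correlation, limma unadjusted p under 0.05 at 3 members). It passed camera without Control replicate 2 (0.00129), within a range of 0.00129 to 0.837 over all alternatives with the preset correlation. Of 18 glucocorticoid response genes 1 rose adjusted over the list alone, and the list had a median log2 fold change of 0.061 (camera adjusted p = 0.866, adjusted p = 0.95 with an estimated correlation, limma unadjusted p under 0.05 at 2 members). With Control replicates 1, 2 and 3 and KC-Tie2 replicates 1, 2 and 3 left out in turn, risen members over all genes numbered 0, 1, 0, 0, 0 and 0 for heat shock, 0, 0, 0, 0, 0 and 2 for immediate early, 0, 2, 0, 0, 0 and 0 for circadian and 0, 2, 0, 0, 0 and 2 for glucocorticoid genes. Fallen members numbered 5 of heat shock, 1 of circadian and 1 of glucocorticoid genes without KC-Tie2 replicate 3, 3 of circadian genes without Control replicate 2, and 0 in the other cases. Called members with the replicate block, eBayes without robust, library weights and voom numbered 1, 0, 2 and 0 (fallen) for heat shock, 2, 0, 1 and 0 (risen) for immediate early, 1, 0, 1 and 0 (fallen) for circadian and 1, 0, 1 and 0 (risen) for glucocorticoid genes. Over the list alone, in the order of left-out libraries, there were 0, 2, 0, 0, 0 and 8 fallen heat shock, 0, 3, 0, 0, 0 and 3 risen immediate early, 0, 2, 0, 0, 0 and 0 risen and 0, 9, 0, 0, 0 and 1 fallen circadian, and 1, 2, 1, 0, 0 and 2 risen glucocorticoid genes. After quantile normalization 1 glucocorticoid gene rose.

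Markers of tissues that can come with a dissected kidney gave no called member, over all genes or adjusted over the list alone, in the limma fit used throughout. With the replicate block 2 adipocyte markers fell over all genes and 3 over the list alone. Over the list alone 2 fell with eBayes without robust, 2 without Control replicate 2 and 2 without KC-Tie2 replicate 3. Erythroid genes risen over the list alone numbered 5 without KC-Tie2 replicate 2 and 1 without Control replicate 2. Over the list alone 1 adrenal and 1 skin gene fell without KC-Tie2 replicate 3, and 1 skin gene with library weights. Of 16 adipocyte markers 15 were below 0, with lipoprotein lipase, Lpl, at 16932 ± 4073 and 9019.9 ± 2489. The adipocyte list had a median log2 fold change of -0.74 (camera adjusted p = 0.00687, adjusted p = 0.627 with an estimated correlation, limma unadjusted p under 0.05 at 1 member). Camera no longer called it without Control replicate 1 (0.671) and without KC-Tie2 replicate 2 (0.226), within a range of 3.96e-07 to 0.671 over all alternatives with the preset correlation, and its median was 0.15 without Control replicate 1. The 8 erythroid and blood genes had a median log2 fold change of 0.48 (camera adjusted p = 0.12, adjusted p = 0.629 with an estimated correlation, limma unadjusted p under 0.05 at 0 members). They passed camera without KC-Tie2 replicate 2 (7.26e-07), within a range of 7.26e-07 to 0.648 over all alternatives with the preset correlation. The 3 tested adrenal genes had a median log2 fold change of 0.12 (camera adjusted p = 0.876, adjusted p = 0.924 with an estimated correlation, limma unadjusted p under 0.05 at 0 members). The 11 urothelium and ureter genes had a median log2 fold change of -0.20 (camera adjusted p = 0.384, adjusted p = 0.851 with an estimated correlation, limma unadjusted p under 0.05 at 0 members). They passed camera without Control replicate 3 (0.000214) and without KC-Tie2 replicate 1 (0.0173), within a range of 0.000214 to 0.83 over all alternatives with the preset correlation. The 4 skin keratinocyte genes had a median log2 fold change of -0.47 (camera adjusted p = 0.125, adjusted p = 0.498 with an estimated correlation, limma unadjusted p under 0.05 at 1 member). They passed camera without Control replicate 3 (0.0177) and without KC-Tie2 replicate 1 (0.0492), within a range of 0.0177 to 0.497 over all alternatives with the preset correlation. Krt5 was at 52.3 ± 55.1 and 40.4 ± 27.6, and Krt14 is not among the genes of the table analysed here. Skeletal muscle had 1 tested marker, Eno3, at 72.2 ± 16.1 and 81.9 ± 8.1, and so no set test.

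The authors' deposited table of the same comparison, whose headers write WT for the group labelled Control, held 686 genes at a false discovery rate under 0.05, 321 higher and 365 lower in KC-Tie2 kidneys, and 2257 genes at an unadjusted p under 0.05. All 297 genes called by limma were also called in the authors' deposited table, in the same direction, and 388 further tested genes were called there alone. Log2 ratios of the authors' deposited table and limma's log2 fold changes had a Spearman correlation of 0.988 across genes, which are not independent replicates. The authors' deposited table gave ratios of 33 for C4b and 17 for Fgg, and the limma folds on the log2(value + 1) scale were 33.1 and 16.3. The scales parted at some named genes: the authors' deposited table gave 85 for S100a8, 13.9 for S100a9, 2.6 for Havcr1 and 0.768 for Krt5, where the limma folds were 24, 9.68, 1.89 and 1.01.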

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

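All alternatives below were planned except voom on estimated counts, which was chosen after seeing the data. Against 297 called genes (150 higher, 147 lower), leaving out 1 library gave 48 to 682 calls, 25 to 311 higher and 18 to 371 lower. The lowest total came without KC-Tie2 replicate 2 and the highest without KC-Tie2 replicate 3, and the cause was not tested. Of the 297 genes, 49, 252 and 51 kept their call without Control replicates 1, 2 and 3, and 64, 46 and 280 without KC-Tie2 replicates 1, 2 and 3. The replicate block gave 581 calls (259 higher, 322 lower, 291 shared), library weights 549 (263 higher, 286 lower, 297 shared), an adjusted p under 0.1 593 (295 higher, 298 lower) and a fold of at least 2 67 (38 higher, 29 lower). The cause was not tested for the first 2, and the last 2 differ by their threshold. The labels do not say that the same replicate numbers pair the samples. Deviations of Control and KC-Tie2 replicates 1, 2 and 3 correlated across genes at 0.178, -0.0956 and 0.0173, and Control replicate 3 correlated best with KC-Tie2 replicate 2 (0.26). Deviations from a mean of 3 libraries depend on each other, so these correlations cannot show whether samples were paired. Pseudocounts of 0.5 and 5, no filter, a mean of at least 100, TMM, quantile normalization, fits without robust eBayes and voom gave 204 to 347 calls. The median log2 fold change of all genes lay within 0.00694 of 0 under each of these. With an estimated correlation 0 lists were higher and 0 lower, and fry called 3 higher and 0 lower, against 22 and 8. Camera's preset correlation gave 19 to 23 higher and 6 to 11 lower lists in the other settings. The 13 mitochondrial encoded genes turned direction after quantile normalization (median 0, adjusted p = 0.949), and the cause was not tested. Where their call was lost, the medians of the matrix, nuclear respiratory chain and adipocyte lists also turned sign in some fits without 1 library. None of the 67 called named genes changed sign under any alternative, and 15, 59, 14, 19, 13 and 67 of them kept their call without Control replicates 1, 2 and 3 and KC-Tie2 replicates 1, 2 and 3. The authors' deposited table held 686 genes at an FDR under 0.05 and 2257 at an unadjusted p under 0.05. On the 500 most variable genes the first component held 35.95% of the variance and separated the genotypes too. The planned count models, edgeR and DESeq2, were not run because whole reads were not recovered. Depth limits genes near 10 normalized counts, where 1 estimated count moves a value by about 1.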

Other observations

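The families in this paragraph and the next were chosen after their values were seen, as were the tests for a female kidney, for the share of proximal tubule and for both blood explanations; those for liver RNA, linked segments and other splits of the samples were written before. Carboxylesterase genes, which hydrolyse esters of drugs and lipids, were lower together with Ces1g. All 9 tested members had a log2 fold change below 0 (median -1.004), 2 were called (Ces1g and Ces1e) and 8 fell adjusted over the list alone (camera adjusted p = 3.84e-12, adjusted p = 0.139 with an estimated correlation). Without Control replicates 1, 2 and 3 and KC-Tie2 replicates 1, 2 and 3, the called members numbered 2, 3, 2, 2, 2 and 6. With the replicate block, eBayes without robust, library weights and voom they numbered 7, 6, 5 and 2. Replication-dependent histone genes were higher, with 4 of 46 risen (H3c1, H3c2, H3c3 and H4c8), 8 adjusted over the list alone and a median of 0.35 (camera adjusted p = 1.88e-06, adjusted p = 0.257 with an estimated correlation). In the same order of left-out libraries, the risen histone genes numbered 2, 4, 2, 1, 0 and 6, and 5, 2, 4 and 1 in the same order of alternatives. At a mean of at least 100 only 1 of 20 tested histone genes rose and the median was 0.063, so the shift lay mainly among lower genes. Family members were corrected after a first run, in which the name patterns had also taken in genes of other families (such as Cyp27b1, Cyp46a1, Ighmbp2 and H1f10) and Dhtkd1 had been counted in the kynurenine pathway, which camera then called with the preset correlation.

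In the kynurenine pathway, which breaks down tryptophan, 3 of 10 genes fell (Kmo, Haao and Afmid), also 3 adjusted over the list alone with 1 risen, and Kynu had 149 ± 49.5 in Control and 405 ± 99.7 in KC-Tie2 kidneys (limma adjusted p = 0.0771). The family had a median of -0.05 (camera adjusted p = 0.17, adjusted p = 0.581 with an estimated correlation). Its fallen members numbered 1, 3, 2, 2, 2 and 3 in the same order of left-out libraries, Control replicates 1, 2 and 3 then KC-Tie2 replicates 1, 2 and 3. With the replicate block, eBayes without robust, library weights and voom they numbered 3, 2, 3 and 2. Cytochrome P450 family 2 had 1 fallen of 18 and 6 fallen and 1 risen adjusted over the list alone (median -0.35, camera adjusted p = 0.00256, adjusted p = 0.139 with an estimated correlation). Family 4 had 1 fallen of 13 and 5 adjusted over the list alone (median -0.21, camera adjusted p = 0.042, adjusted p = 0.257 with an estimated correlation). Without single libraries in the same order, fallen members numbered 0, 2, 0, 0, 1 and 5 in family 2 and 0, 1, 0, 0, 1 and 2 in family 4. With the same alternatives, fallen members numbered 5, 2, 3 and 1 in family 2 and 2, 2, 2 and 1 in family 4. Guanylate-binding protein genes had 1 risen of 8 and 2 adjusted over the list alone (median 0.36, camera adjusted p = 0.00256, adjusted p = 0.318 with an estimated correlation), and risen members numbered 0, 1, 0, 1, 0 and 1 without single libraries in the same order. Aldo-keto reductase genes had 0 called of 14 and 2 fallen adjusted over the list alone (median -0.24, camera adjusted p = 0.00599, adjusted p = 0.265 with an estimated correlation), and fallen members numbered 0, 0, 0, 0, 0 and 2 in that order. They numbered 1, 0, 2 and 0 with the replicate block, eBayes without robust, library weights and voom. UDP-glucuronosyltransferase (12 genes), immunoglobulin constant (4) and glutathione S-transferase genes (17) had camera adjusted p of 0.731, 0.0831 and 0.731, with 0.855, 0.321 and 0.855 with an estimated correlation. Over all genes 2 UDP-glucuronosyltransferase and 2 immunoglobulin constant genes fell, and 1 glutathione S-transferase gene rose and 1 fell.

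The male-biased kidney genes had a median log2 fold change of -0.86, but none of the 16 was called over all genes tested in the limma fit used throughout. The camera call (adjusted p = 3.96e-15) was lost with an estimated correlation (adjusted p = 0.403). The authors' deposited table did call the members named by the rule, Cyp4a12a (ratio 0.0832, FDR 1.3e-08) and Kap (ratio 0.511, FDR 0.018). A female kidney among the KC-Tie2 libraries is argued against by the Y-linked genes, whose lowest sum in a KC-Tie2 library was 80.42% of the Control mean. A lower share of all proximal tubule cells as the whole cause is argued against by 20 proximal tubule markers outside the sex-biased lists. Their median was -0.165 (SE 0.0751), above -0.43, which is 0.5 of the male-biased median. This test left out Acsm2, Cyp2e1 and Slc7a13 and did not separate parts of the proximal tubule. It therefore cannot address a loss of cells from a single part. If the list is lower, a weaker androgen signal in KC-Tie2 males may account for it, but hormone levels were not measured and the ages and strains are not in the labels, so this stays an untested hypothesis.

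The fibrinogen genes Fgg and Fgb and the complement genes C4b and Cfi rose, and liver makes most of these proteins. Liver RNA in the KC-Tie2 samples was tested on abundant hepatocyte transcripts, of which 11 of 24 were tested, and their median log2 fold change was 0.122 (SE 0.216). Albumin, Alb, the most abundant of them in liver, had 124 in Control and 81.1 in KC-Tie2 kidneys (limma adjusted p = 0.134), while Apob (17456 ± 246) and Ttr (1624 ± 541) were also abundant in Control kidneys. Liver RNA is thereby argued against. Transcription in the kidney under circulating cytokines may account for the rises, but neither its site nor any cytokine level was measured, so this stays an untested hypothesis.

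Neutrophil genes rose, and they can come from cells in the tissue or in residual blood. More blood of unchanged composition would leave the ratio of S100a8, S100a9 and Csf3r to haemoglobin alike in both genotypes. That ratio was 0.457%, 0.805% and 0.951% in the Control and 2.93%, 12.9% and 1.48% in the KC-Tie2 libraries. The log2 difference was 2.44 (SE 0.975), and the groups did not overlap. These 3 genes were the called neutrophil markers, and Hdc was left out, so the choice of genes partly set a higher ratio. The test therefore cannot decide on more blood. In KC-Tie2 replicate 2, haemoglobin was below the Control mean. The 3 genes still summed to 118.4 there, against 8.4, 17.3 and 13.5 in the Control libraries. Residual blood richer in neutrophils and neutrophils in the kidney cannot be told apart: the lowest haemoglobin level of a KC-Tie2 library was 50.95% of the Control mean, in KC-Tie2 replicate 2, with 274.6% and 217.5% in replicates 1 and 3, so blood was present in each.

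Genes near a transgene can differ by strain rather than by disease. Of the 297 called genes, 51.52% had another called gene of another name family within 2 Mb, against a median of 47.81% and a 95th percentile of 53.2% over 10000 random draws (share of draws as high 0.146). Linked segments of another strain therefore stay undecided, as genotype and any such segment cannot be told apart by this test. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real split, called as many as 297 genes, and the highest of the others called 0. These splits are too few for a share under 0.05.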
